A study of Gallus gallus with 6 samples.

How the data were processed

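RNA sequencing data from HD11 chicken macrophage-like cells were used, 3 mock libraries and 3 libraries from cells given 100 ng/mL recombinant chicken IFN-beta for 3 h. The labels describe the libraries of each group as independent biological replicates, put all 6 in one batch and state paired-end sequencing of total RNA. Groups and replicate numbers were taken from the sample titles.

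The authors deposited a table of gene read counts, which per the values are expected counts, since 2322 genes had a count that was not whole in at least 1 library. The authors also deposited a table of TPM (transcript abundance normalised for length and depth) for the same 14903 genes and, per the file headers, a table of their own comparison with log2 fold changes, p-values and adjusted p-values for 14879 genes. Per the submitters' processing notes the genome build was GRCg6a and DESeq2 was used. The aligner, the counting tool, the annotation version and the strand setting are not given in the sources used here. Where reads of near-identical or overlapping genes were divided or left out by that counting, the levels of those genes are uncertain. The table of counts had no row without a gene.

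Gene symbols were those of the deposited tables. A RefSeq table of the assembly GRCg7b matched 13998 of the 14903 gene identifiers and was used only for names and for which genes neighbour each other, and no coordinates are given. It names the genes listed as USP18, IDI1, CCAH221, CNKSR2L and BLNK in the deposited tables USP41, IDI2, LOC417536, LOC101749809 and SH2D6. In the deposited data 8 symbols have the form of a calendar date, as spreadsheets make of the MARCH genes, and these were matched by identifier.

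Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were removed with filterByExpr at its defaults, leaving 11091 genes and 3812 not tested, and libraries were scaled by TMM factors, which were 1.03 to 1.04 in mock and 0.963 to 0.973 in IFN-beta. A quasi-likelihood model with the group as its only term was fitted (glmQLFit, glmQLFTest), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The biological coefficient of variation was 3.56%. Log2 fold changes have edgeR's prior count, and group levels are scaled CPM. The test gives no SE. The SE shown is the absolute log2 fold change over the square root of the F statistic, an approximation that can be too small for large changes. With totals of 15665594 to 15885227 counts per library, differences in depth between libraries were small. For genes with few mock reads the counting interval of the fold is an exact binomial one at 95%, which covers counting error only, since reads are not independent molecules.

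Before the data were examined, the tests, the alternatives, 22 gene lists with 617 entries, 5 of them of other cell types, and the rule for named genes were fixed. The rule took the 12 genes with the largest and the 12 with the lowest log2 fold change among called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups, 20 genes always reported, and from each list up to 4 called members with the smallest adjusted p, or the 2 members with the highest level where none was called. Of the list entries, 512 were found by symbol, 8 by the reference symbol and 97 were not matched. Of the 20 fixed genes 18 were tested. Genes named outside the rule are said to be so, and a few genes that the rule takes are not reported here. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over 20 lists with at least 2 tested members. Camera compares a list with the other genes. No list had a median, mean and test that differed in sign.

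Libraries of a group were compared pairwise with a chi-square test over genes with at least 20 counts in the pair. The statistic was 1.67 to 4.48 times its degrees of freedom, so all pairs within a group differed by more than sampling noise. This cannot tell separate cultures from repeat preparations of 1 culture. Each library was counted as 1 replicate because the labels describe independent biological replicates. Groups of 3 are too small for a test of outlying libraries, and an exact permutation test of 3 against 3 cannot give a p under 0.1.

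Alternatives for the gene test were DESeq2 1.42.0, its size factors within edgeR, upper quartile factors, library size alone, no filter on low counts, a mean of at least 1 CPM, the replicate number as a block, a test against a 1.5-fold change (glmTreat), limma on log2(TPM + 1) and log2(TPM + 0.1) with a mean TPM of at least 1 and on log2(TPM + 1) without that filter, and leaving out each library in turn. Those for lists were an estimated correlation, fry, the block, DESeq2 size factors, no filter, removal of members of the antiviral list and leaving out each library. Counts of list members under each scaling, a correction for transcript length and the removal of the 50 most induced genes were chosen after seeing the data. Agreement with the authors' deposited table was counted per gene.

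The scripts were tested on counts simulated for the comparison of IFN-beta with mock over 11091 genes, of which 200 were changed. Of 50 genes changed at each size, 37 were recovered at 1.2-fold, 45 at 1.5-fold, 49 at 2-fold and 50 at 4-fold, each in the right direction, and 16 of 10891 unchanged genes were called. Camera called 0 of 20 unchanged lists. Genes were simulated independently of each other, so this does not test how correlation between genes affects camera. The changed genes were drawn from those with at least 20 expected counts and were far fewer than the genes called in the data.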

Results

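Gene expression was measured by paired-end RNA sequencing in HD11 cells, a chicken line with the character of macrophages. The study compared 3 mock libraries with 3 libraries of cells given recombinant chicken interferon beta (IFN-beta), a type I interferon cytokine, at 100 ng/mL for 3 h. No time was recorded here for the mock libraries, so a mock matched at 3 h is not assumed. The deposited table gave counts for 14903 genes, with totals of 15665594 to 15885227 per library, and 13388 to 13465 genes had a count above 0 in a library. The 20 most abundant genes took 8.84 to 9.42% of each total. Levels are given as CPM, which are counts scaled to the effective library size, as mean ± SD with n = 3 libraries per group, and fold changes are those of IFN-beta over mock fitted by edgeR. Spearman correlations of log2 CPM across genes were 0.997 to 0.999 between libraries of a group and 0.975 to 0.976 between groups. The first principal component held 81.1% of the variance, with the 3 mock libraries on one side and the 3 IFN-beta libraries on the other.

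The comparison of IFN-beta with mock addressed the early transcriptional response of these cells to a type I interferon. Antiviral genes led the increases. OASL, an oligoadenylate synthetase-like antiviral protein, rose from 5.94 ± 1.45 to 1005 ± 29.98 CPM, a log2 fold change of 7.40 (SE 0.07), and IFIT5, an RNA-binding interferon-induced protein, rose from 26.7 ± 4.45 to 4159 ± 110.3 CPM (7.28, SE 0.07). SAMD9L, a restriction factor, rose from 2.12 ± 0.0287 to 207 ± 13.8 CPM, MX1, a dynamin-like antiviral GTPase, rose from 0.493 ± 0.162 to 47.4 ± 2.14 CPM, and TRANK1 rose from 22.1 ± 0.222 to 1490.1 ± 53.3 CPM. The largest decrease was in FBXO32, which encodes the muscle atrophy-associated ubiquitin ligase subunit atrogin and fell from 30.5 ± 1.42 to 3.30 ± 0.188 CPM (-3.20, SE 0.10). The edgeR adjusted p (Benjamini-Hochberg) was 1.3e-23 for OASL, 6.6e-24 for IFIT5 and 7.3e-16 for FBXO32. These SE are approximate. For OASL the counting interval of its fold, 151 to 191, was wider than its SE would give.

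Among the 12 largest increases past the naming rule were also secreted factors and a feedback inhibitor. CSF3, the granulocyte colony-stimulating factor, rose from 0.123 ± 0.0619 to 9.06 ± 0.846 CPM. Its mock level rested on 6 reads over 3 libraries, so its fold of 69.1 has a counting interval of 33.5 to 201, which covers counting error only. The chemokine genes K123 (43.1-fold), CCAH221 (40.0-fold) and IL8L2, a chicken counterpart of interleukin 8 (35.1-fold), rose, as did SOCS3, a suppressor of cytokine signalling (38.8-fold). MARCKSL1, an actin-binding protein, rose 52.2-fold, and IFI6, an interferon-induced membrane protein, rose 35.2-fold.

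The 12 largest decreases included surface receptors and regulators of survival. TLR5, the flagellin receptor, fell from 12.6 ± 1.27 to 2.91 ± 0.434 CPM, and P2RY10, a G protein-coupled receptor, fell from 10.1 ± 0.653 to 1.74 ± 0.106 CPM. BMF, a pro-apoptotic member of the BCL2 family, fell from 19.1 ± 2.16 to 3.69 ± 0.520 CPM, and TP53INP1, a stress-induced nuclear protein, fell from 22.2 ± 1.06 to 5.19 ± 0.994 CPM. The gene MCF2L2 was 5.80-fold lower, the glucose transporter gene SLC2A12 5.50-fold lower and IKZF3, a zinc finger transcription factor of lymphocytes, 3.96-fold lower. ZNF395, CNKSR2L and the unnamed locus LOC427826 were 4.19-fold, 4.07-fold and 4.88-fold lower. Each of the 12 largest decreases and of the 12 largest increases had every library of one group above every library of the other, which the rule required.

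**Figure D1:**
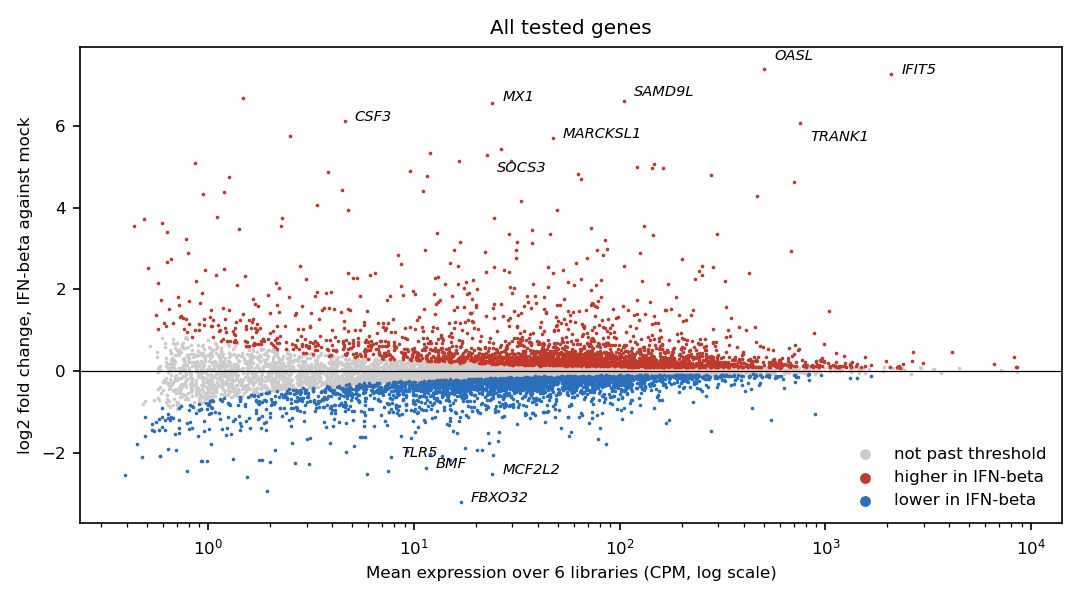
Log2 fold change of IFN-beta over mock (vertical axis) against mean expression over the 6 libraries in CPM (log axis) for the 11091 tested genes. Red and blue points are the 2697 genes higher and the 2480 genes lower in IFN-beta by edgeR, and grey points did not pass; OASL lies at 7.40 and FBXO32 at -3.20.

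The list of antiviral effectors moved upward nearly as a whole. Of 34 tested members, 31 rose, 2 fell and 1 did not pass (32 rose and 2 fell when adjusted over the list alone). CMPK2, a mitochondrial nucleotide kinase, rose from 9.95 ± 0.590 to 314 ± 8.85 CPM, ZNFX1, a helicase that senses viral RNA, rose from 159 ± 3.03 to 1204 ± 26.9 CPM, and EIF2AK2, the double-stranded RNA-activated kinase, rose from 7.09 ± 0.323 to 37.9 ± 1.202 CPM. The median log2 fold change of the list was 1.65, and camera (limma) placed it above the other genes with a Benjamini-Hochberg adjusted p of 1.4e-20. RSAD2, the antiviral enzyme viperin, was fixed for report but was removed by the filter on low counts, with 2 reads over all 6 libraries.

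Sensors of nucleic acids and microbes went both ways. Of 29 tested members, 15 rose, 7 fell and 7 did not pass, and the counts were the same when adjusted over the list alone, with 13 that rose and 8 that fell under library size alone (median 0.08) and 12 and 8 on log2(TPM + 1) (0.05). IFIH1, the cytosolic RNA sensor MDA5, rose from 20.8 ± 1.39 to 242 ± 6.23 CPM, TRIM25, a ubiquitin ligase of RNA sensing, rose from 20.4 ± 1.93 to 145 ± 5.03 CPM, and TLR15, a Toll-like receptor of birds and reptiles, rose from 22.4 ± 1.84 to 97.2 ± 1.62 CPM. TLR7, an endosomal receptor for single-stranded RNA, fell from 84.6 ± 1.22 to 28.0 ± 0.253 CPM. TLR3, with 15 reads in mock and 41 in IFN-beta, was removed by the filter on low counts. With no filter it was called (log2 fold change 1.51, SE 0.45, edgeR adjusted p 0.0146, Benjamini-Hochberg), while in the authors' deposited table its adjusted p was 0.0627. The list median was 0.17, with an adjusted p of 0.0260 by camera (limma, Benjamini-Hochberg) and an adjusted p of 0.226 with an estimated correlation. With the members shared with the antiviral list removed, the adjusted p by camera was 0.0575.

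In the list of interferon receptors, JAK kinases, STAT and IRF factors, 11 of 19 tested members rose, 5 fell and 3 did not pass, also when adjusted over the list alone. Under library size alone 9 rose and 5 fell (median 0.09), and 8 rose and 5 fell among 18 on log2(TPM + 1) (0.08). STAT2, a component of the transcription complex downstream of the type I receptor, rose from 5.78 ± 0.472 to 16.6 ± 0.267 CPM. The transcription factor genes IRF1 and IRF7 rose from 8.24 ± 0.794 to 83.6 ± 2.23 CPM and from 29.8 ± 2.87 to 81.7 ± 3.73 CPM. Both chains of the type I interferon receptor fell, IFNAR1 from 121 ± 1.35 to 80.9 ± 3.14 CPM and IFNAR2 from 59.7 ± 3.92 to 52.3 ± 0.126 CPM, which is 1.49-fold and 1.14-fold. The median log2 fold change over the list was 0.19, with an adjusted p of 0.0141 by camera (limma, Benjamini-Hochberg) and an adjusted p of 0.107 with an estimated correlation.

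Negative feedback genes rose in 12 of 21 tested members, fell in 5 and did not pass in 4, also when adjusted over the list alone. On log2(TPM + 1) 10 of 20 rose and 7 fell, with a median of 0.32. USP18, a protease that restrains signalling from the type I receptor, rose from 45.1 ± 0.511 to 882 ± 9.90 CPM. SOCS1 and SOCS3, inhibitors of JAK kinases, rose from 4.11 ± 1.28 to 25.7 ± 2.15 CPM and from 1.13 ± 0.152 to 44.2 ± 2.70 CPM, and NFKBIA, the inhibitor of NF-kappaB, rose from 29.3 ± 1.49 to 116 ± 6.81 CPM. Over the tested members the median log2 fold change was 0.69, with an adjusted p of 0.00771 by camera (limma, Benjamini-Hochberg) and an adjusted p of 0.107 with an estimated correlation. Of 6 listed interferon genes 4 were found in the deposited tables, and the filter on low counts removed these. Over the 6 libraries IFNA3 had 2 reads, IFNW1 2, IFNKL1 10 and IFNG 30, of which 27 were in IFN-beta. With no filter IFNG was called (log2 fold change 3.10, edgeR adjusted p 0.000592, Benjamini-Hochberg; 0.0106 in the authors' deposited table) and the other 3 were not.

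**Figure D2:**
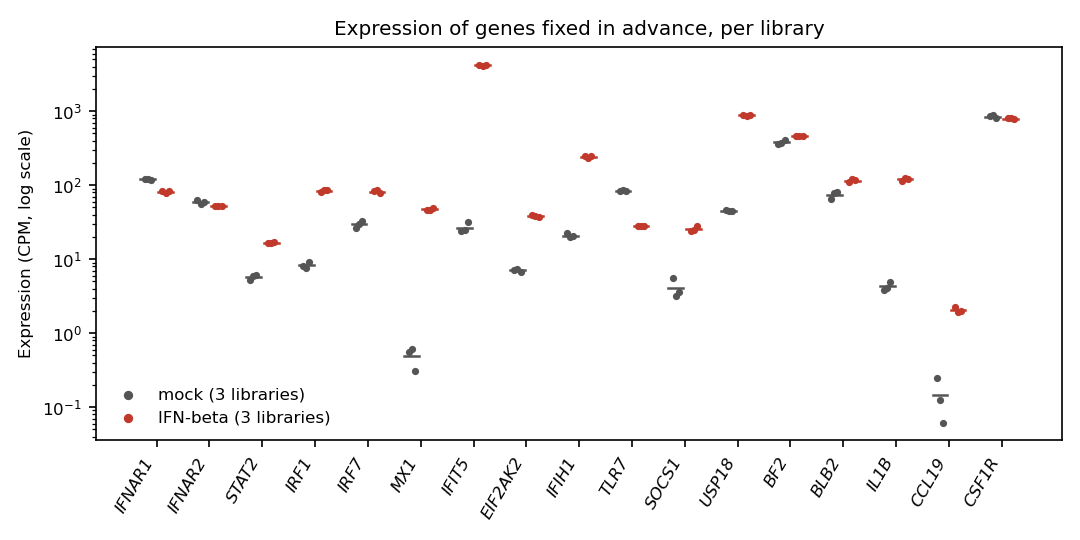
Expression in CPM (log axis) of tested genes fixed in advance, in each of 3 mock (grey) and 3 IFN-beta (red) libraries, with lines at the group means. IFIT5 stood at 26.7 CPM in mock and 4159 CPM in IFN-beta, whereas IFNAR1 stood at 121 and 80.9 CPM.

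Cytokine, chemokine and inflammatory enzyme genes rose in 18 of 29 tested members, fell in 4 and did not pass in 7, also when adjusted over the list alone. IL1B, an inflammatory cytokine, rose from 4.28 ± 0.600 to 121 ± 6.99 CPM, IL18 rose from 72.2 ± 0.877 to 431 ± 13.4 CPM, and the chemokine gene CCLI7 rose from 8.94 ± 0.914 to 278 ± 16.8 CPM. CCL19, a chemokine that guides lymphocytes and dendritic cells, rose from 0.144 ± 0.0946 to 2.06 ± 0.182 CPM, with 7 reads in mock and a counting interval of its fold of 6.70 to 36.6. Named after their values were seen, IL12B fell from 8.20 ± 0.489 to 3.24 ± 0.275 CPM, while IL6 stood at 4.81 ± 0.209 and 5.71 ± 0.910 CPM and PTGS2 at 3.76 ± 0.591 and 4.59 ± 0.676 CPM in mock and IFN-beta and did not pass. The list median was 1.47, with an adjusted p of 4.1e-07 by camera (limma, Benjamini-Hochberg). Of 38 members found, the filter removed those low in both groups. It kept CCL19 and CSF3, with 7 and 6 reads in mock, through their IFN-beta counts. This can raise the share that rose and the median. With no filter on low counts, the adjusted p by camera was 1.0e-07 over 38 members. On log2(TPM + 0.1), where 23 members were tested, the median was 2.37.

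Of 21 tested members of the NF-kappaB pathway, 15 rose, none fell and 6 did not pass (17 rose when adjusted over the list alone). On log2(TPM + 1) 13 rose and 1 fell, with a median of 0.49, which was 0.82 on log2(TPM + 0.1). NFKB1, a subunit of the factor, rose from 88.9 ± 1.40 to 197 ± 2.45 CPM, NFKBIZ, a nuclear regulator of it, rose from 28.6 ± 0.767 to 134 ± 3.62 CPM, and BIRC2, a ubiquitin ligase that inhibits apoptosis, rose from 75.0 ± 1.84 to 409 ± 15.1 CPM. The median log2 fold change over the list was 0.97, with an adjusted p of 1.6e-08 by camera (limma, Benjamini-Hochberg).

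Immediate early genes rose in 23 of 31 tested members, fell in 3 and did not pass in 5, also when adjusted over the list alone. BTG2, an antiproliferative gene, rose from 26.5 ± 1.14 to 265 ± 11.01 CPM, DUSP5, a phosphatase of ERK kinases, rose from 3.35 ± 0.282 to 45.3 ± 0.718 CPM, PIM1, a kinase gene, rose from 7.09 ± 0.162 to 55.5 ± 2.23 CPM, and FOSL2, a subunit of the transcription factor AP-1, rose from 91.0 ± 3.31 to 262 ± 8.64 CPM. Over the tested members the median log2 fold change was 1.04, with an adjusted p of 2.0e-09 by camera (limma, Benjamini-Hochberg) and an adjusted p of 0.0559 with an estimated correlation.

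Both antigen presentation lists had a median log2 fold change of 0.16. In the MHC class I list, 12 of 20 tested members rose, 2 fell and 6 did not pass (13 rose and 2 fell when adjusted over the list alone). The counts and the median depended on the scaling. Under library size alone 9 rose and 2 fell (median 0.06), and on log2(TPM + 1) 7 rose and 3 fell (0.04). Relative to the median of all genes, the list median was 0.16 and 0.14 under these scalings. BF2, the main class I heavy chain of the chicken, rose from 382 ± 19.9 to 459.5 ± 4.48 CPM, and the peptide transporter genes TAP1 and TAP2 rose from 6.002 ± 0.646 to 15.0 ± 0.467 CPM and from 31.5 ± 1.68 to 44.5 ± 2.64 CPM. LNPEP, an aminopeptidase of cross-presentation, fell from 174 ± 4.69 to 127 ± 3.87 CPM. The list median was 0.16, with an adjusted p of 0.00609 by camera (limma, Benjamini-Hochberg) and an adjusted p of 0.173 with an estimated correlation.

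In the MHC class II list, 7 of 14 tested members rose, 2 fell and 5 did not pass, also when adjusted over the list alone, against 6 and 3 under library size alone (median 0.07) and 6 and 4 of 15 on log2(TPM + 1) (0.02). CIITA, the transactivator of class II genes, rose from 12.5 ± 0.330 to 47.0 ± 2.39 CPM, BLB2, a class II beta chain, rose from 74.7 ± 7.64 to 115 ± 5.05 CPM, and CD74, the invariant chain, rose from 599 ± 41.1 to 803 ± 30.1 CPM. The median log2 fold change over the list was 0.16 and the list did not pass, with an adjusted p of 0.0562 by camera (limma, Benjamini-Hochberg). That p was 0.0320 without mock replicate 3 and 0.0426 with no filter on low counts. BF2 and BLB2 have near-identical copies, BF1 and BLB1, so the split of reads between the copies is uncertain.

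Ubiquitin and ISGylation-related genes rose in 13 of 22 tested members, fell in 5 and did not pass in 4 (13 rose and 6 fell when adjusted over the list alone). The excess of increases shrank to 11 that rose and 7 that fell under library size alone (median 0.07) and to 8 and 7 on log2(TPM + 1) (0.04). Relative to the median of all genes, the list median was 0.17 and 0.15 under these scalings. USP25, a deubiquitinase, rose from 87.5 ± 2.21 to 245 ± 3.06 CPM, and DTX3L, a ubiquitin ligase, rose from 35.1 ± 0.165 to 112 ± 5.71 CPM. Over the tested members the median log2 fold change was 0.17, with an adjusted p of 0.00771 by camera (limma, Benjamini-Hochberg), an adjusted p of 0.107 with an estimated correlation and 0.0575 without the members of the antiviral list.

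Genes of macrophage identity and phagocytosis went both ways. Of 30 tested members, 13 rose, 9 fell and 8 did not pass (16 rose and 9 fell when adjusted over the list alone), and on log2(TPM + 1) 9 rose and 9 fell among 29, with a median of 0.02. CEBPB, a transcription factor of myeloid cells, rose from 52.4 ± 3.51 to 348 ± 12.6 CPM, CD83, an activation marker, rose from 19.4 ± 2.26 to 153 ± 4.18 CPM, and SPI1, the myeloid factor PU.1, rose from 558 ± 16.5 to 869.6 ± 20.6 CPM. CSF1R, the receptor of macrophage colony-stimulating factor, was 1.06-fold lower, at 846 ± 33.7 and 795 ± 10.2 CPM. Its edgeR adjusted p (Benjamini-Hochberg) was 0.0468, and it did not pass without mock replicate 1 or 2 or without IFN-beta replicate 1, 2 or 3 (adjusted p 0.0798 to 0.303), nor with no filter on low counts (0.0751) or in the authors' deposited table (0.0530). The list median was 0.13, with an adjusted p of 0.152 by camera (limma, Benjamini-Hochberg).

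In the cell death list, 18 of 32 tested members rose, 8 fell and 6 did not pass (18 rose and 9 fell when adjusted over the list alone), which became 14 and 11 under library size alone (median 0.08) and 13 and 10 on log2(TPM + 1) (0.05). The members with the smallest p included effectors of death and inhibitors of it. MLKL, the executor of necroptosis, rose from 3.49 ± 0.609 to 62.6 ± 0.945 CPM, and APAF1, the scaffold of the apoptosome, rose from 42.6 ± 4.36 to 91.5 ± 3.69 CPM, while MCL1, an anti-apoptotic BCL2-family member, rose from 166 ± 8.01 to 490.4 ± 17.5 CPM and BIRC2, another inhibitor of apoptosis, rose by the values given above. The median log2 fold change over the list was 0.17, with an adjusted p of 0.00654 by camera (limma, Benjamini-Hochberg) and an adjusted p of 0.107 with an estimated correlation.

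Cholesterol synthesis and handling genes rose in 25 of 30 tested members, fell in 2 and did not pass in 3 (26 rose and 2 fell when adjusted over the list alone). Fewer rose under library size alone, 17 with 2 that fell (median 0.20), and on log2(TPM + 1), 16 of 29 with 1 that fell (0.17). HMGCS1 and IDI1, enzymes of the mevalonate pathway, rose from 245 ± 18.4 to 445 ± 10.4 CPM and from 609.6 ± 10.2 to 1159 ± 22.7 CPM. STARD4, a sterol carrier, rose from 124 ± 6.15 to 322 ± 7.33 CPM, and CH25H, the cholesterol hydroxylase, rose from 3.37 ± 0.186 to 30.01 ± 1.01 CPM. Over the tested members the median log2 fold change was 0.29, with an adjusted p of 1.4e-07 by camera (limma, Benjamini-Hochberg) and an adjusted p of 0.107 with an estimated correlation.

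Unfolded protein and heat shock genes rose in 22 of 29 tested members, fell in 2 and did not pass in 5 (23 rose and 2 fell when adjusted over the list alone), against 20 and 4 under library size alone (median 0.27) and 18 and 4 on log2(TPM + 1) (0.24). The cytosolic chaperone genes HSPH1 and HSP90AA1 rose from 235 ± 3.11 to 419 ± 9.25 CPM and from 2227 ± 11.8 to 3092 ± 144 CPM, and HSPA5, the chaperone BiP of the endoplasmic reticulum, rose from 604 ± 18.6 to 859.7 ± 17.2 CPM. The list median was 0.37, with an adjusted p of 2.5e-06 by camera (limma, Benjamini-Hochberg) and an adjusted p of 0.131 with an estimated correlation.

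Cell cycle genes fell in 21 of 43 tested members, rose in 7 and did not pass in 15 (21 fell and 8 rose when adjusted over the list alone). More fell under library size alone, 28 with 4 that rose (median -0.19), and on log2(TPM + 1), 28 of 42 with 4 that rose (-0.22). MKI67, a marker of proliferating cells, fell from 337 ± 22.4 to 257 ± 7.52 CPM. CDKN1A, an inhibitor of cyclin-dependent kinases, rose from 3.39 ± 0.307 to 11.4 ± 0.669 CPM, and CDK6, a kinase of cell cycle entry, rose from 190.4 ± 14.9 to 254 ± 8.76 CPM. The median log2 fold change over the list was -0.10 and the list did not pass, with an adjusted p of 0.0562 by camera (limma, Benjamini-Hochberg). That p was 0.0464 without mock replicate 3 and 0.0442 with no filter on low counts.

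Of 21 tested glycolysis genes, 7 rose, 2 fell and 12 did not pass, also when adjusted over the list alone, but scaling by library size alone gave 5 that rose and 9 that fell, upper quartile scaling 5 and 6, and the TPM values 4 and 10. HK2, a hexokinase, rose from 101 ± 3.38 to 187 ± 5.22 CPM, HIF1A, the hypoxia factor, rose from 192 ± 8.26 to 275 ± 7.72 CPM, and the hexokinase gene HK1 fell from 283 ± 6.63 to 209 ± 4.80 CPM. Over the tested members the median log2 fold change was 0.02, with an adjusted p of 0.318 by camera (limma, Benjamini-Hochberg). The sign of this median turned negative under those 3 scalings (-0.04 to -0.10). Relative to the median of all genes, it stayed at 0.007 to 0.020 under each scaling.

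**Figure D3:**
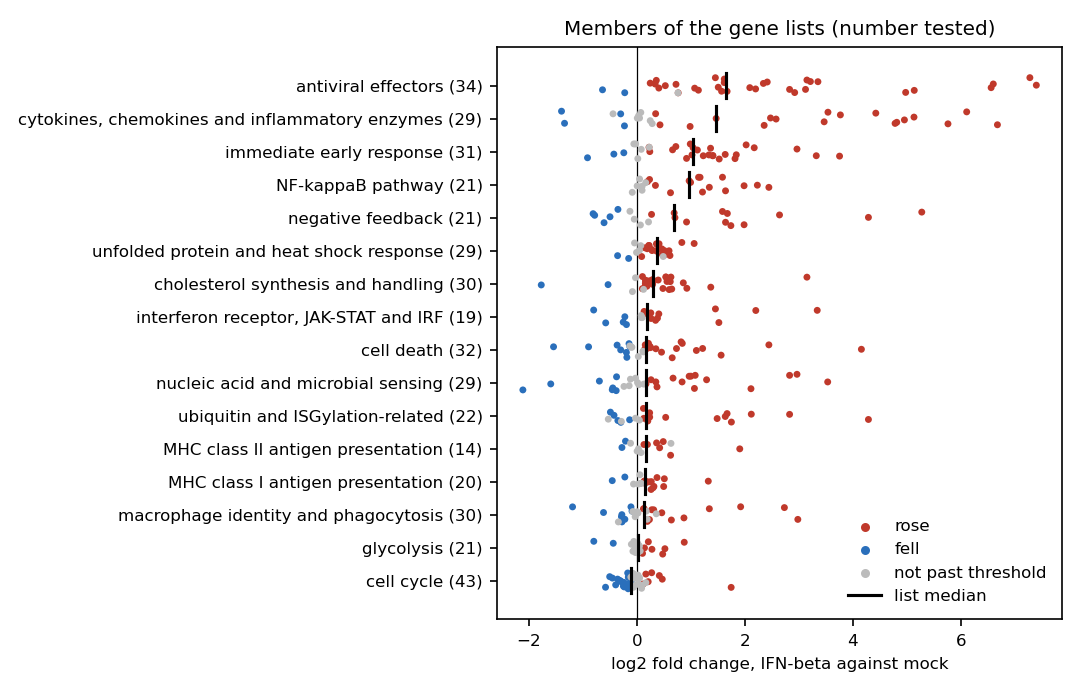
Log2 fold change of IFN-beta over mock (horizontal axis) for the tested members of each gene list, with the number tested in parentheses, red for genes that rose, blue for genes that fell and grey for genes that did not pass by edgeR; black lines are list medians. Lists of markers of other cell types are not drawn. Among the lists drawn, the median was highest for antiviral effectors (1.65) and lowest for the cell cycle (-0.10), but on log2(TPM + 1) it was highest for the cytokine list (2.19, with 23 members tested, against 1.92 for antiviral effectors), and that of glycolysis (0.02) turned negative under library size, upper quartile and TPM scaling. Relative to the median of all genes, the glycolysis median stayed at 0.007 to 0.020.

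Of 88 listed markers of other cell types, 54 were found in the deposited tables and 18 were tested, and those not found say nothing about these cell types. The T and NK cell markers had 1 tested gene, CD247, at 1.60 ± 0.313 and 1.28 ± 0.264 CPM in mock and IFN-beta, which did not pass. None of the 4 tested B cell markers passed, with CHIR-AB1 at 25.2 ± 1.83 and 24.9 ± 0.573 CPM and BLNK, named SH2D6 by the reference, at 9.93 ± 1.15 and 8.76 ± 0.451 CPM, and neither did the 2 tested erythroid and thrombocyte markers, TAL1 and GP1BA. BLNK did pass with library size alone or on the TPM values, and TAL1 on the TPM values, both lower in IFN-beta. Of 5 tested fibroblast and stroma markers 3 fell, FBN1 from 99.6 ± 4.31 to 78.0 ± 3.10 CPM, FAP from 51.7 ± 4.13 to 40.3 ± 2.98 CPM and COL5A1 from 24.5 ± 1.10 to 16.9 ± 1.14 CPM. Of 6 tested epithelial and endothelial markers 3 rose and 1 fell. ERG, an ETS transcription factor of endothelial and other cells, rose from 429 ± 13.8 to 617 ± 16.1 CPM, KRT7 rose from 4.30 ± 0.352 to 7.32 ± 0.470 CPM, and ELF3 rose from 0.103 ± 0.0355 to 2.28 ± 0.387 CPM. ELF3 had 5 reads in mock, and its fold had a counting interval of 9.22 to 69.8. PECAM1 fell from 20.3 ± 0.769 to 15.4 ± 1.43 CPM. None of the 4 marker lists tested by camera passed.

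Across all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 5177 of 11091 tested genes, 46.7%, of which 2697 were higher and 2480 lower in IFN-beta. A change of at least 2-fold was seen in 362 of the higher and 194 of the lower genes, and 3927 of the calls, 75.9%, were under 1.5-fold. The spread behind these calls was small, with a biological coefficient of variation of 3.56%. Higher genes were 52.1% of the calls, and the split moved with the scaling. It was 2020 higher and 3356 lower (37.6% higher) with upper quartile factors, 1734 and 4008 (30.2%) with library size alone, and 1376 and 3823 (26.5%) on log2(TPM + 1), where the median of all genes shifted by -0.11 against the fold changes reported here. Taken relative to the median of all genes on log2(TPM + 1), the medians of the MHC class I, ubiquitin, cholesterol and cell cycle lists were 0.14, 0.15, 0.27 and -0.12. Those of the sensing, receptor, MHC class II and cell death lists were 0.15, 0.18, 0.12 and 0.15. A test against a change of 1.5-fold (edgeR's glmTreat) called 662 genes. Of the 20 lists tested by camera, 12 passed, and 3 did with an estimated correlation, those of antiviral effectors, cytokines and the NF-kappaB pathway (adjusted p 0.0188, 0.0382 and 0.0430). For the receptor and negative feedback lists the estimated correlation was -0.033 and -0.012, under the preset 0.01. A higher correlation between genes thus does not account for the loss of these lists. The other lists that were lost had estimates of 0.013 to 0.141. Reads of BF2, BLB2, CCAH221, CCLI7, CHIR-AB1, FAP, GP1BA, HK1, IL18, MCL1, MKI67, NFKBIZ and TLR7 were not whole numbers in at least 1 library. The counting tool is not given, so the source of the fractions is not known. If reads were shared with another feature, the levels of these genes are uncertain to that extent.

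The authors' deposited table holds their own comparison of the same groups. In the authors' deposited table, 4031 of 14879 genes had an adjusted p under 0.05, 2200 higher and 1831 lower in IFN-beta. Of these, 4002 were also called by edgeR here, each in the same direction. Of the 29 others in the authors' deposited table, 28 were not tested here because of low counts, and 1175 genes were called by edgeR only. Across the 11091 genes in both, Pearson's r of the log2 fold changes was 0.9999 and the Spearman coefficient 0.9998, a description across genes, which are not independent replicates.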

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

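Calls shared with an alternative never differed in sign from those reported, for any of the alternatives run. The number of called genes stayed within 1.5 times 5177 except under the test against 1.5-fold (662, with 416 higher and 246 lower), which by construction drops small changes. Leaving out each library gave 4353 to 5430 genes. With library size alone 1734 genes were higher and 4008 lower. On log2(TPM + 1) these were 1376 and 3823, on log2(TPM + 0.1) 1377 and 3815, and on log2(TPM + 1) without a filter 1395 genes were higher. Genes at least 2-fold higher numbered 219 on log2(TPM + 1) and 222 without its filter, and 87 were at least 2-fold lower in both, where the added 1 shrinks the change of low genes. TPM and library size alone lack the TMM factor, which was higher in mock. Requiring 2-fold in both tables left 511 genes called both by the authors' deposited table and by edgeR. With an estimated correlation 3 of the 20 lists passed camera. Of the refits of the 98 named genes, 1621 kept their direction and side of the threshold, 31 lost the call (the test against 1.5-fold, plus CSF1R with no filter and in 5 refits that each left out a library) and 6 gained it (BLNK and TAL1), none with another sign. Of the refits of lists, 217 kept theirs, 12 lost and 10 gained it, 6 of the gains under fry, which does not compare a list with other genes. The labels give no pairing of libraries by replicate number, and the main model had none. Deviations from the group means correlated weakly for equal numbers, at 0.0831, 0.0755 and 0.0675. Each library nevertheless correlated best with its own number, a hint from the data only, so a pairing is not excluded. With the replicate number as a block 5869 genes were called, and among lists the sensing list was lost (camera adjusted p 0.0520) and no other call changed among lists and named genes. Of the low-count genes RSAD2, TLR3, IFNA3, IFNW1, IFNKL1 and IFNG, which the filter removed, TLR3 and IFNG were called with no filter.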

Other observations

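The genes of the first paragraphs, and the test of neighbouring genes, were chosen after the values were seen. Outside the fixed lists, genes of metabolism and of secreted products were among the large increases. ACOD1, which makes the antimicrobial metabolite itaconate, rose from 7.38 ± 0.482 to 236 ± 7.04 CPM, AVD, the biotin-binding egg white protein avidin, rose from 11.8 ± 0.943 to 133 ± 7.42 CPM, and ADM, the peptide hormone adrenomedullin, rose from 0.987 ± 0.225 to 21.1 ± 0.827 CPM. HERC4L rose from 8.51 ± 0.507 to 286 ± 3.29 CPM, the Notch ligand gene JAG2 rose from 6.27 ± 0.619 to 68.3 ± 1.62 CPM, and the metalloreductase gene STEAP4 rose from 6.43 ± 0.283 to 57.2 ± 3.81 CPM. Receptor and signalling genes were among the decreases. GPR34, a receptor of microglia and macrophages, fell from 132 ± 4.602 to 38.3 ± 1.66 CPM, the phospholipase gene PLCB2 fell from 116 ± 7.28 to 44.3 ± 2.05 CPM, and GAB3, an adaptor of CSF1R signalling, fell from 100.0 ± 4.16 to 41.2 ± 3.02 CPM. BHLHE41, a transcription repressor, fell from 238 ± 5.35 to 98.5 ± 2.17 CPM, and FUT7, which makes selectin ligands, fell from 34.1 ± 0.770 to 8.89 ± 0.712 CPM.

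Genes that rose at least 2-fold were often neighbours in the reference order of the tested genes. Untested genes between them were left out of this order, so neighbours here need not be adjacent in the genome. Among 347 such genes with a place in that order, 60 neighbouring pairs were both higher, against a mean of 11.2 and a maximum of 30 over 10000 random draws (permutation p 0.0001, the smallest they can give). Of 185 genes at least 2-fold lower, 12 neighbouring pairs were both lower, against a mean of 3.16 and a maximum of 12, so at least 1 draw gave as many (permutation p 0.0002). Runs included the chemokine genes CCL4 and CCL5, the genes PARP14, DTX3L and PARP9, and CH25H with LIPA and IFIT5. Tandem copies of one gene share reads and regulation and were not removed from this count. RSAD2 had 2 reads over all 6 libraries, while CMPK2, its neighbour in the reference, rose from 9.95 ± 0.590 to 314 ± 8.85 CPM; the cause was not tested.

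The tests below were specified before their results were seen, but on patterns found in the same data. Some of their genes had already been tested in the lists above. Cytokine and chemokine genes rose beside the antiviral genes, and a Toll-like receptor agonist such as endotoxin in the recombinant protein could contribute. It predicts a rise of NF-kappaB feedback genes, and the 10 listed had a median log2 fold change of 1.16, with 7 that rose and none that fell (camera p 1.8e-06, and p 0.00756 with an estimated correlation). These 10 belong to the NF-kappaB list described above and would also rise if IFN-beta itself raised that list, so the test does not favour an agonist over IFN-beta. IL6 (0.25), PTGS2 (0.28) and IL12B (-1.34) were noted after their values were seen and exclude nothing. Both explanations stay open, since no library separates the cytokine from its preparation.

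Calls covered 46.7% of the tested genes, mostly with small changes. Log2 fold change and transcript length had a Spearman correlation of -0.18 across genes, yet removing the length trend kept 90.2% of the calls (4669 of 5177, among 5841 calls after the removal, with the measure set to kept calls after the total was seen), which argues against that trend as the whole cause. With the 50 most induced genes left out before scaling, 98.5% of the calls among other genes were kept (5048 of 5127). TMM scaling already trims genes with extreme changes, so this removal could alter little. It does not test a shift in the counts that is spread over many genes. The real split of the libraries was 1 of 10 into 3 and 3, too few for a share under 0.05, with 5177 genes against at most 0 in another split by edgeR (at most 625 at an unadjusted p under 0.05 and 3 by DESeq2). Every other split mixes mock and IFN-beta libraries on both sides. Their difference then counts as spread within a side, so few calls were bound to result and these counts are no measure of chance. A broad response to IFN-beta and a difference in handling between the groups both remain possible and were not separated by these libraries.

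FBXO32, BMF and TP53INP1, known targets of FOXO transcription factors, were among the largest decreases, and lower FOXO activity is a hypothesis for them. With SESN3 and PDK4, seen at the same time, their median log2 fold change was -2.09, and it was -2.08 after removal of the length trend. The trend thus made up little of these decreases. Since the genes were picked as among the lowest, so weak a trend could hardly have explained them, and the test had little chance of another outcome. Of 21 further tested targets, 12 fell and 5 rose, with a median of -0.26, between the values fixed for and against the hypothesis (camera p 0.0344, and p 0.222 with an estimated correlation). CDKN1B and BCL2L11 among them had already been tested in the cell cycle and cell death lists. CCNG2 and BCL6, also FOXO targets, rose (1.45 and 1.29). CCNG2 lay in a run of 4 neighbouring tested genes that rose at least 2-fold, so its rise may not bear on FOXO activity. The further targets leave it open whether FOXO activity may be lower.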
